A study of Mus musculus with 15 samples.

How the data were processed

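The series holds 15 samples, of which the 6 RNA libraries of WT and dKO fibroblasts were analysed and the 9 others (immunoprecipitated or input DNA and nucleosome samples) were not analysed here. Per the labels, RNA was depleted of ribosomal RNA and made into stranded libraries. The submitters' notes name bcl2fastq 2.17.1.14, TopHat2 2.0.14 with Bowtie, HTSeq 0.6.1 and DESeq2 1.16.1 on the mm9 genome. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited table has 23829 genes, of which 22085 matched the reference names by identifier. Per the file headers, it holds the raw read count of each gene in each library, which was the input to every test here. It also holds a signal in which the authors divided the count by a size factor per library and by the gene length in kilobases, and this relation was checked on the values. The authors' own comparison is deposited as a log2 ratio of WT over dKO with a p-value and an adjusted p-value per gene. That log2 is 1.24 for H2afz, 1.25 for H2afv and −1.14 for Ifit1, and 1.25 is its largest absolute value, so it was used only for its calls and its direction.

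Groups followed the labels, with 3 WT and 3 dKO libraries. Library totals ran from 32804851 to 44185983 reads, so that a floor of 3 reads corresponds to between 0.0679 and 0.0914 CPM. Such floors cover counting error only. The 10 most abundant genes took 12.3 to 13.2% of the reads of a library, mitochondrial ribosomal RNA 3.76 to 4.38% and the small nuclear RNA 7SK 3.01 to 3.51%. No library stood out as a copy of another. Replicate numbers are shared by the groups, but no label pairs them. After group means were removed, libraries with the same number correlated across 9924 genes at r between −0.11 and −0.04, where genes are not independent replicates, so no pairing was used in the tests reported.

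The tests were run in R 4.3.3. Counts were filtered with filterByExpr, scaled by TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 on group alone, with a Benjamini-Hochberg threshold of 0.05 over the 14929 genes kept. The common biological coefficient of variation was 3.15%. At an unadjusted threshold of 0.05, 3886 genes would pass. Fold changes are dKO over WT. CPM values are scaled by TMM, and errors are SDs over 3 libraries or SEs of the fitted log2 change. Gene lists numbered 37, written from textbook knowledge before the data were examined, as were the main test, the alternatives and the rule for naming genes. The 35 lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists. With that setting 14 passed, and 4 of them (interferon, immediate early, p53 and senescence-associated genes) passed with an estimated correlation. By fry, which asks whether a list's genes move on balance in one direction, 10 passed, and 25 passed for change in either direction; fry does not compare a list with other genes.

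Genes named are H2afz and H2afv, the 10 largest rises and falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, the 5 smallest p-values in each direction, and up to 4 members of each list by p-value. Names that are provisional or duplicated were passed over, which removed 7 genes among the falls. Other genes named are members that make up a small count of a list, chosen after their values were seen. A gene that the rule selects is not reported here.

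On simulated data with 14750 genes, 50 genes per fold were changed, all with a log2 mean CPM of at least 1. Among these, edgeR recovered 80% of 1.25-fold changes, 98% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes. Of its 200 calls, 11 were false. Recovery of changes in rarely read genes was not tested. None of 200 lists of unchanged genes passed camera there. The simulated genes varied independently, so this does not test the preset correlation.

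The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, upper quartile factors, library totals alone, no filter, at least 10 reads in 3 libraries, the replicate number as a block, the most abundant genes left out, each library left out in turn, a threshold of 0.01 and an estimated correlation in camera. Removal of trends with abundance and with gene length, the lists without shared members, and 2 further lists were added after the data had been seen. Promoter CpG content was planned only for the case that a genome sequence was at hand, and was not analysed here. Figures were drawn with matplotlib 3.10.9.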

Results

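Total RNA was measured by sequencing in mouse embryonic fibroblasts from mid-gestation embryos, in which both genes of the histone variant H2A.Z, H2afz and H2afv, carry sites for the Cre recombinase. The WT cells received a control adenovirus and the double knockout (dKO) cells an adenovirus that carries Cre, so both groups had been infected. RNA was taken 3 days later from cells described as confluent and resting. Each group had 3 libraries, of 39270916, 41540646 and 33083084 counted reads in WT and 32804851, 44185983 and 34560388 in dKO. Between 20065 and 20671 genes had at least 1 read in a library, and 14929 genes were tested. The first principal component, with 32.7% of the variance, separated the groups. The second, with 19.9%, spread the dKO libraries, with replicate 1 at 17.4 and replicate 3 at −18.0, while dKO replicate 2 and the WT libraries lay between −0.63 and 1.17. The mean chi-square per gene between pairs of libraries, which counting error alone puts near 1, was 2.14 to 3.45 within WT, 3.44 to 6.69 within dKO and 6.82 to 13.4 between the groups. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

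The first comparison asked whether the targeted genes were lost in dKO. H2afz (ENSMUSG00000037894) fell from 83.8 ± 3.07 to 11.8 ± 2.31 CPM (counts scaled to library size; SD, n = 3 per group). H2afv (ENSMUSG00000041126) fell from 79.6 ± 1.66 to 14.04 ± 2.49 CPM. These are log2 changes of −2.83 (SE 0.069; edgeR adjusted p = 1.57e-17) and −2.51 (SE 0.065; edgeR adjusted p = 2.88e-17), and each dKO library lay below each WT library. The dKO libraries kept 14.1% ± 2.76 (SD, n = 3) of the mean WT level of H2afz and 17.6% ± 3.13 of that of H2afv. The share left was higher for H2afv than for H2afz in each dKO library, at ratios of 1.30, 1.22 and 1.23. The table counts whole genes, so it does not say which exons these reads came from.

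**Figure D1:**
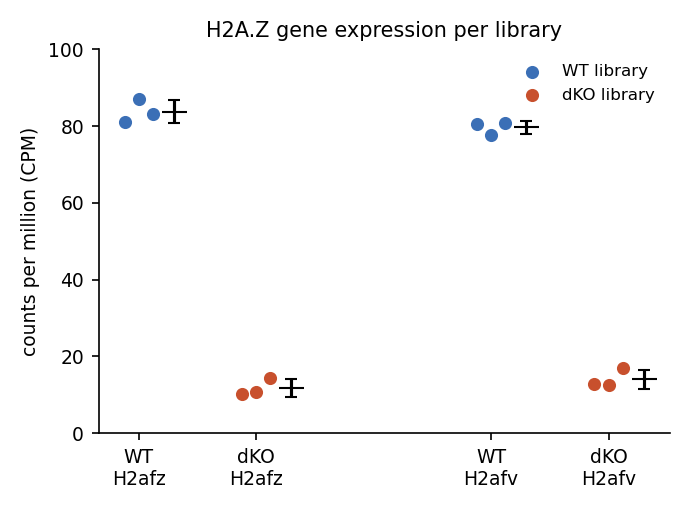
Expression in CPM of H2afz and H2afv in each library, with the mean and SD (n = 3) of each group beside the points. The dKO libraries lie between 10.3 and 16.9 CPM and the WT libraries between 77.7 and 87.1 CPM.

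The second comparison asked which other genes differed between dKO and WT. Among genes with a mean log2 CPM of at least 1 and no overlap between the groups, most of the largest rises were in interferon-stimulated and immediate early genes, and the named falls other than H2afz and H2afv were all smaller than 2-fold. The 10 largest rises among these genes were in Oas2 (log2 change 1.60), Hist2h3c1 (1.47), Mx1 (1.41), Rsad2 (1.39), Ier2 (1.32), Cxcl10 (1.30), Cmpk2 (1.29), Ifi44 (1.27), Ifit1 (1.24) and Egr1 (1.24). Of these, Oas2, Mx1, Rsad2, Cxcl10, Cmpk2, Ifi44 and Ifit1 are induced by interferon, whereas Ier2 and Egr1 respond within minutes to growth factors and stress. Hist2h3c1 is the deposited symbol of a histone H3 gene with near-identical copies, but the reference names its identifier (ENSMUSG00000070392) Gm20634, so its identity and its value are uncertain. Under the same limits the largest falls after the targeted genes were in Kcnn1 (−0.77), Stap2 (−0.65), Cys1 (−0.61), Ccdc39 (−0.60), Fxyd1 (−0.59), H2-DMb1 (−0.59), Myo1h (−0.58) and Vsig10l (−0.58).

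In all, 957 genes were higher and 668 lower in dKO by the edgeR quasi-likelihood test, which is 10.9% of the genes tested. The median change was 0.17 on the log2 scale (interquartile range 0.12 to 0.29) for higher genes and −0.21 for lower genes. The groups did not overlap for 920 of the 957 and 653 of the 668. Over all tested genes they did not overlap for 4397 (29.5%), where chance gives 10%. At least 2-fold changes numbered 53, with 38 higher and 15 lower. Of the 38, 18 were on the interferon list, 4 on the immediate early list (Fos, Egr1, Junb and Ier2) and 16 on neither. Most of these 16 were rarely read, with a mean log2 CPM under 1 and as low as −1.96. Of the 15, 2 were the H2A.Z genes, and the other 13 were rarely read, with a mean log2 CPM of at most −0.40. One of the 38, Gm12913, chosen after its values were seen, rests on dKO replicate 3, which has 4392 reads against 40 to 79 in the other libraries, and its log2 change is −0.44 without that library (edgeR adjusted p = 0.262).

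The split between higher and lower genes depends on how the libraries were scaled. It was 957 to 668 with TMM factors, 706 to 856 with upper quartile factors and 559 to 1339 with library totals alone, which move the median of all genes by −0.033 on the log2 scale. DESeq2 gave 720 higher and 375 lower, with 29 changed at least 2-fold. Without WT replicate 1, 2 or 3 the higher genes numbered 621, 573 and 598 and the lower genes 403, 319 and 338, and without dKO replicate 2 the lower genes numbered 437. Among the named falls, Cys1 no longer passed without WT replicate 2 (adjusted p = 0.0570), and Fxyd1 without WT replicate 3 (adjusted p = 0.0756). Myo1h (adjusted p = 0.0884) and Vsig10l (adjusted p = 0.0791) no longer passed with DESeq2. Nor did Myo1h without WT replicate 2 (adjusted p = 0.124) or dKO replicate 2 (0.0872), or Vsig10l without WT replicate 1 (0.0716), WT replicate 2 (0.0504), dKO replicate 2 (0.0633) or dKO replicate 3 (0.0544). The deposited comparison by the authors lists 582 genes higher and 276 lower in dKO, of which 849 were also called here, all 849 in the same direction.

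**Figure D2:**
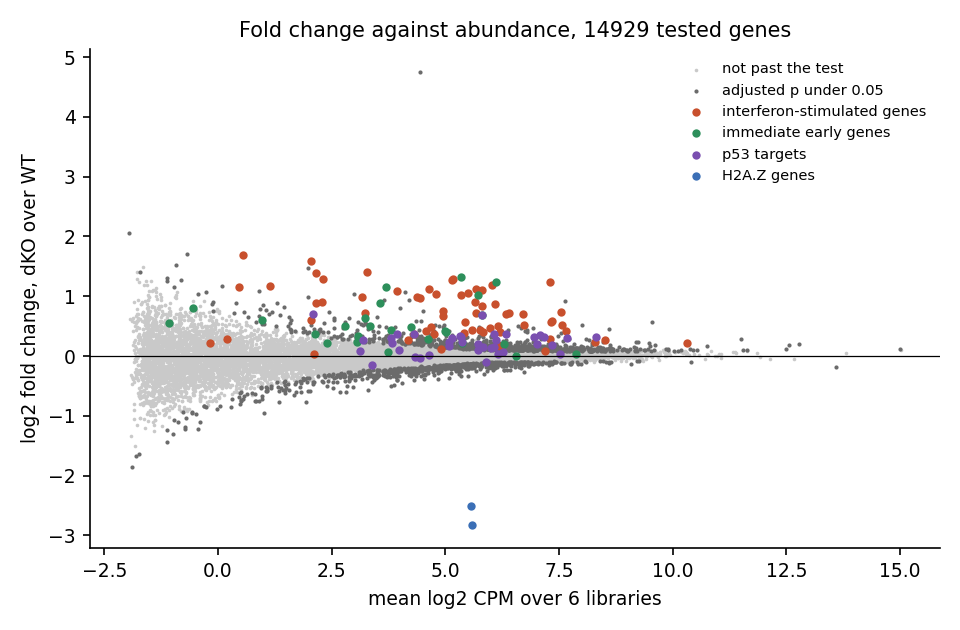
Log2 fold change (dKO over WT) against mean log2 CPM over the 6 libraries for 14929 tested genes, with 4 gene groups in colour. Interferon-stimulated and immediate early genes lie mostly above 0 over a wide range of abundance, H2afz and H2afv lie far below it, and the point above 4 is Gm12913, whose log2 fold change of 4.75 comes from 1 library.

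Genes induced by interferon, which act in antiviral defence and antigen presentation, rose as a group in dKO. Of 63 tested members, 58 were higher and 0 lower over all genes, and 60 were higher when adjusted over the list alone. The median log2 change was 0.71, which is 1.64-fold, and the groups did not overlap for 59 of the 63 (10% by chance). Summed over the list, the level went from 4313 ± 102 to 6004 ± 141 CPM (SD, n = 3). Ifit1, a sensor of viral RNA, rose from 93.2 ± 3.98 to 220.4 ± 12.3 CPM (edgeR adjusted p = 4.24e-16). Isg15, a ubiquitin-like modifier, rose by 1.18 on the log2 scale, the chemokine Cxcl10 by 1.30 and Ifit3 by 1.10. The members that did not pass were Ifit2, Tap2, Gbp5, Oas3 and Isg20. The list was higher relative to other genes by camera (adjusted p = 3.73e-286, and adjusted p = 0.0266 with an estimated correlation). The interferon genes searched for, Ifng not among them, were close to the limit of detection. The 5 found were Ifnab, Ifnb1, Ifna2, Ifne and Ifnz. They had at most 4 reads in a library, with 9 reads in all WT and 18 in all dKO libraries. The 14 macrophage markers in the table summed to between 7.82 and 9.37 CPM per library.

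Immediate early genes, most of which encode transcription factors and phosphatases switched on by growth factors and stress, also rose. Of 26 tested members, 18 were higher and 0 lower over all genes, and 22 higher and 0 lower when adjusted over the list alone, with a median log2 change of 0.46. Ier2 rose from 23.3 ± 0.761 to 58.1 ± 5.12 CPM, Egr1 from 41.6 ± 2.59 to 97.9 ± 11.1 CPM, and Junb by 1.02 and Btg2 by 0.69 on the log2 scale. By camera the list passed (adjusted p = 3.16e-45, and adjusted p = 0.0274 with an estimated correlation). Btg2 is also on the p53 list. Without this shared member, a test chosen after the data were seen, camera gave adjusted p = 5.30e-39, and adjusted p = 0.0368 with an estimated correlation. Among contractile genes and targets of the serum response factor, 7 of 30 were higher and 1 lower over all genes (10 higher and 2 lower adjusted over the list alone). Cyr61, a matricellular protein, rose from 137.9 ± 0.144 to 261.6 ± 10.7 CPM and Ctgf rose by 0.17 on the log2 scale, while Tagln fell by 0.18. That list passed by camera (adjusted p = 1.29e-04) but not with an estimated correlation (adjusted p = 0.238 with an estimated correlation).

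Targets of p53, the transcription factor of the DNA damage response, rose by less. Of 38 tested, 25 were higher and 0 lower over all genes, and 29 higher and 1 lower when adjusted over the list alone, with a median log2 change of 0.23. Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 0.37, Mdm2, which targets p53 for degradation, by 0.32, and Ccng1 by 0.33 (camera adjusted p = 9.63e-28, and adjusted p = 0.0276 with an estimated correlation). In the p53 list 9 members are on other lists too, among them Btg2, Gtse1 and Ckap2, and the list was not tested without them. Of 34 tested genes of the senescence-associated secretory list, 12 were higher and 1, Mmp9, was lower over all genes (15 higher and 1 lower adjusted over the list alone). They included Ccl5 (0.94), Igfbp3 (0.48), Cxcl10 and Cdkn1a, and 14 members are on other lists too. The median log2 change was 0.08 (camera adjusted p = 5.42e-12, and adjusted p = 0.0266 with an estimated correlation). Without the members shared with the interferon and p53 lists, a test chosen after the data were seen, 9 of 30 were higher and 1 lower (11 higher and 1 lower adjusted over the list alone). The camera call then held with the preset correlation (adjusted p = 7.64e-06) but was lost with adjusted p = 0.0716 with an estimated correlation.

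**Figure D3:**
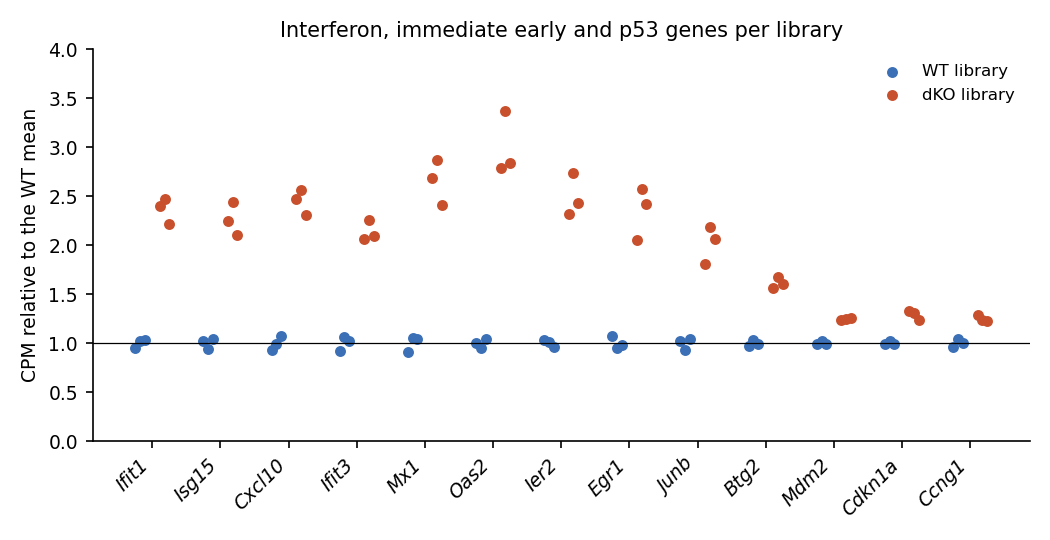
Expression in CPM of 13 named interferon, immediate early and p53 genes in each library, divided by the mean of the 3 WT libraries. For each gene the 3 dKO libraries lie above the 3 WT libraries.

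In the integrated stress and unfolded protein response list, 19 of 37 genes were higher and 1, Sel1l, was lower over all genes (27 higher and 1 lower adjusted over the list alone), with a median log2 change of 0.12. Trib3 rose by 0.29, Sesn2 by 0.34, Aldh1l2 by 0.28 and Ddit3, a transcription factor of the stress response, by 0.22. The camera adjusted p was 2.02e-13, and the call was lost with adjusted p = 0.105 with an estimated correlation. Of 22 NF-kB targets, 8 were higher, among them Ccl7 (0.58), Ptgs2 (0.58), Ier3 (0.42) and Cxcl1 (0.66), and 2 were lower, C3 and Birc3 (9 higher and 3 lower adjusted over the list alone). Their camera call (adjusted p = 1.17e-04) was also lost, with adjusted p = 0.261 with an estimated correlation. Of 18 heat shock genes, 6 were higher and 0 lower (9 and 0 adjusted over the list alone), the clearest being Hspa4l (0.23), with a camera call (adjusted p = 8.31e-04) that gave adjusted p = 0.360 with an estimated correlation. Of 23 targets of NRF2, 8 were higher, among them Hmox1 (0.24), and 1 was lower, Gstm2 (−0.45), with 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0540, and adjusted p = 0.498 with an estimated correlation). With the preset correlation the NRF2 list passed with DESeq2 (adjusted p = 0.00453) and limma-voom (0.0123).

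Other histone genes rose in part. Of 54 replication-dependent histone genes, which have near-identical copies and are therefore uncertain, 14 were higher and 0 lower over all genes (18 and 0 adjusted over the list alone), with a median of 0.12 and Hist1h1c at 0.23 and Hist1h1d at 0.24. Of 13 genes listed as other replication-independent histone genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone), namely H1f0 (0.29), H3f3b (0.19), Hist3h2a (0.57) and Cenpa (0.11). Hist3h2a bears the name of a histone cluster gene, like members of the replication-dependent list, so the lists do not divide sharply by class. Both lists passed by camera (adjusted p = 2.82e-08 and 8.10e-04) and neither did with an estimated correlation (adjusted p = 0.596 and adjusted p = 0.482 with an estimated correlation). Among 54 genes of G2/M and mitosis, 17 were higher and 0 lower (26 and 0 adjusted over the list alone), with a median of 0.07. They included Gtse1 (0.27), Ckap2 (0.18), Kif23 (0.16) and the kinase Aurka (0.16), with a camera adjusted p = 1.20e-07 and adjusted p = 0.498 with an estimated correlation. Gtse1 and Ckap2 are also on the p53 list. Without these shared members, 15 of 52 were higher and 0 lower (22 and 0 adjusted over the list alone), with a median of 0.07. Camera then gave adjusted p = 2.25e-06, and adjusted p = 0.557 with an estimated correlation. Of 50 genes of G1/S and DNA replication, 3 were higher, Rrm2 (0.17), Rfc5 and Orc6, and 0 lower (3 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.235). Its median of 0.02 turns negative with library totals alone. Summed over tested members, the G2/M list reached 8864 ± 85.7 CPM in WT and 9276 ± 159 CPM in dKO (SD, n = 3). The G1/S list reached 5957 ± 29.0 and 6048 ± 69.2 CPM. Transcripts of cell division were thus present in both groups, although the cells are described as resting. The calls of Cenpa, Rfc5 and Orc6 were lost when some single libraries were left out, with adjusted p up to 0.160, 0.127 and 0.174. These 3 calls were also lost with DESeq2 (adjusted p = 0.0778, 0.0611 and 0.0661), upper quartile factors (0.0715, 0.0570 and 0.0553) and library totals alone (0.141, 0.127 and 0.116), that of Cenpa with limma-voom (0.0541) and that of Rfc5 with the replicate number as a block (0.0540).

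Several lists of abundant housekeeping and matrix genes moved by little. Of 53 collagen and matrix genes, 20 were higher, among them Col18a1 (0.43), Col5a3 (0.27), Postn (0.19) and Col1a1 (0.29), and 3 were lower, Eln, Lox and Lum (22 higher and 5 lower adjusted over the list alone). Their median was 0.04, and their camera call (adjusted p = 0.00203) gave adjusted p = 0.706 with an estimated correlation. Of 78 cytosolic ribosomal protein genes, 18 were higher and 0 lower (29 and 0 adjusted over the list alone), with a median of 0.06. Their camera adjusted p of 2.85e-05 became adjusted p = 0.706 with an estimated correlation and 0.100 without dKO replicate 1. Of 32 genes of glycolysis and hypoxia, 7 were higher, among them Pfkl (0.15) and Ddit4 (0.24), and 0 lower (11 higher and 1 lower adjusted over the list alone). Their camera adjusted p of 0.00281 became adjusted p = 0.501 with an estimated correlation and 0.0699 without dKO replicate 1. Of 23 cholesterol synthesis genes, 3 were higher, among them Insig1 (0.16), and 1, Pmvk, was lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.200). Of 49 nuclear oxidative phosphorylation genes, 2 were higher (Cox5a and Atp5b) and 1, Sdhd, was lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.718). Of 11 mitochondrially encoded genes, 3 were higher, mt-Nd2, mt-Atp6 and mt-Co2, and 0 lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.162). Without dKO replicate 1 the nuclear and the mitochondrially encoded lists passed, downward and upward (camera adjusted p = 0.0331 and 0.00784 with the preset correlation). With all libraries and an estimated correlation, camera gave these lists adjusted p = 0.955 and 0.592. The call of Pmvk was lost whichever of the 6 libraries was left out (adjusted p up to 0.183) and with DESeq2 (0.0825) and the replicate block (0.0510). With some single libraries left out, the calls of Cox5a, Atp5b, Sdhd, mt-Atp6 and mt-Co2 were lost, with adjusted p up to 0.140, 0.153, 0.115, 0.0715 and 0.180. The call of mt-Nd2 was lost with DESeq2 (adjusted p = 0.0785), that of Cox5a with library totals alone (0.0586), and those of Atp5b and mt-Co2 with upper quartile factors (0.0584 and 0.0579) and library totals alone (0.153 and 0.126).

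Lists of chromatin regulators and of genes under chromatin control did not pass camera. By fry, which does not compare a list with other genes, the H3.3 list passed upward (adjusted p = 0.0260). For change in either direction, fry passed that list (adjusted p = 0.00159) and those of H2A.Z exchange (0.00217), DNA methylation (0.00100), Polycomb (1.39e-05), Hox (0.0169), imprinted (4.19e-04) and Wnt, Notch and BMP genes (6.56e-04). In the complexes that exchange H2A.Z and its chaperones, 1 of 30 genes was higher (Epc1, 0.11) and 1 lower (Ruvbl1, −0.14), with 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.776). H3f3b was the 1 gene higher of 11 for H3.3 and its chaperones, with 0 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.584), and the sign of that list's median, 0.02, turns with library totals alone. Of 23 DNA methylation and demethylation enzymes, 0 were higher and 1, Tet2 (−0.13), was lower (0 and 1 adjusted over the list alone; camera adjusted p = 0.927). The median of that list was 0.02, its mean −0.01 and its test pointed down, and the median turns negative with library totals alone. Suz12 (0.13) and Pcgf3 (0.13) were the 2 genes higher of 33 Polycomb and trithorax subunits, with 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.994). Of 8 tested genes on the list named for germline genes with methylated CpG island promoters, 0 passed in either direction (0 adjusted over the list alone, camera adjusted p = 0.828). Only these 8 of the 30 genes of that list measured had enough reads to be tested, and they summed to 11.6 ± 0.784 CPM in WT. They include Pou5f1 and Nanog, which are better known as pluripotency genes. Promoter CpG content and methylation were not analysed here, so the name of the list was not checked for its members. Of 23 Hox genes, 0 passed (0 adjusted over the list alone, camera adjusted p = 0.731). Of 27 imprinted genes, Igf2r (0.14), Peg10 (0.23), Mest (0.11) and Plagl1 (0.12) were the 4 higher and 0 were lower (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.964). The median and mean of the imprinted list were −0.02 and −0.03 while its test pointed up. Of 33 Wnt, Notch and BMP response genes, 4 were higher, Notch1 (0.19), Notch3 (0.40), Id1 (0.15) and Bambi (0.22), and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.233). The call of Epc1 was lost whichever of the 6 libraries was left out (adjusted p up to 0.199), with DESeq2 (0.0966), with upper quartile factors (0.0754), with library totals alone (0.144) and with the replicate number as a block (0.0640). With some single libraries left out, the calls of Ruvbl1, Tet2, Mest, Plagl1 and Bambi were lost, with adjusted p up to 0.126, 0.0862, 0.0505, 0.168 and 0.226. The calls of Tet2, Plagl1 and Bambi were also lost with DESeq2 (adjusted p = 0.0654, 0.0677 and 0.0677), those of Plagl1 and Bambi with upper quartile factors (0.0695 and 0.0642), and those of Mest, Plagl1 and Bambi with library totals alone (0.0583, 0.122 and 0.0815).

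Markers of other cell types gave few calls. Of 5 tested macrophage markers, 1 was higher, Mpeg1 (1.07, from 0.510 ± 0.135 to 1.04 ± 0.417 CPM), and 0 lower (1 and 0 adjusted over the list alone), and its call was lost without WT replicate 2 (adjusted p = 0.153), WT replicate 3 (0.0681) or dKO replicate 2 (0.248). Perp, Sfn and Krt19 were the 3 higher of 10 epithelial markers, with 0 lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.121), and Perp is also a p53 target. The epithelial list had a median of 0.25, above that of the p53 list, and passed camera with library totals alone (adjusted p = 0.0432). With TMM factors, camera gave it adjusted p = 0.501 with an estimated correlation. Without the member shared with the p53 list, camera gave adjusted p = 0.306 with the preset correlation. Pax3 was the 1 higher of 7 skeletal muscle markers, with 0 lower (1 and 1 adjusted over the list alone). Col10a1 (0.29) was higher and Comp (−0.27) lower among 12 cartilage and bone markers (1 and 1 adjusted over the list alone). Fasn was the 1 higher of 8 adipocyte genes, with 0 lower (2 and 0 adjusted over the list alone); that list had a median of −0.01, a mean of 0.04 and a test that pointed up. Among 10 endothelial, 12 neural and 3 hepatocyte markers 0 passed (0 adjusted over the list alone for each), and 0 blood markers had enough reads to be tested. The call of Sfn was lost whichever of the 6 libraries was left out (adjusted p up to 0.175) and with DESeq2 (0.181), limma-voom (0.0662), upper quartile factors (0.0539), library totals alone (0.0583) and the replicate block (0.0709). The calls of Krt19, Pax3, Comp and Fasn were lost when some single libraries were left out, with adjusted p up to 0.220, 0.124, 0.162 and 0.187. Those of Krt19, Pax3 and Comp were also lost with DESeq2 (adjusted p = 0.110, 0.127 and 0.146), and those of Krt19 and Comp with limma-voom (0.0663 and 0.0514). With upper quartile factors and library totals alone, Krt19 (0.0591 and 0.0706) and Fasn (0.0628 and 0.129) did not pass, and Comp did not with the replicate number as a block (0.0556). The camera adjusted p-values of these lists lay between 0.121 for epithelial markers and 0.911 for cartilage and bone markers.

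**Figure D4:**
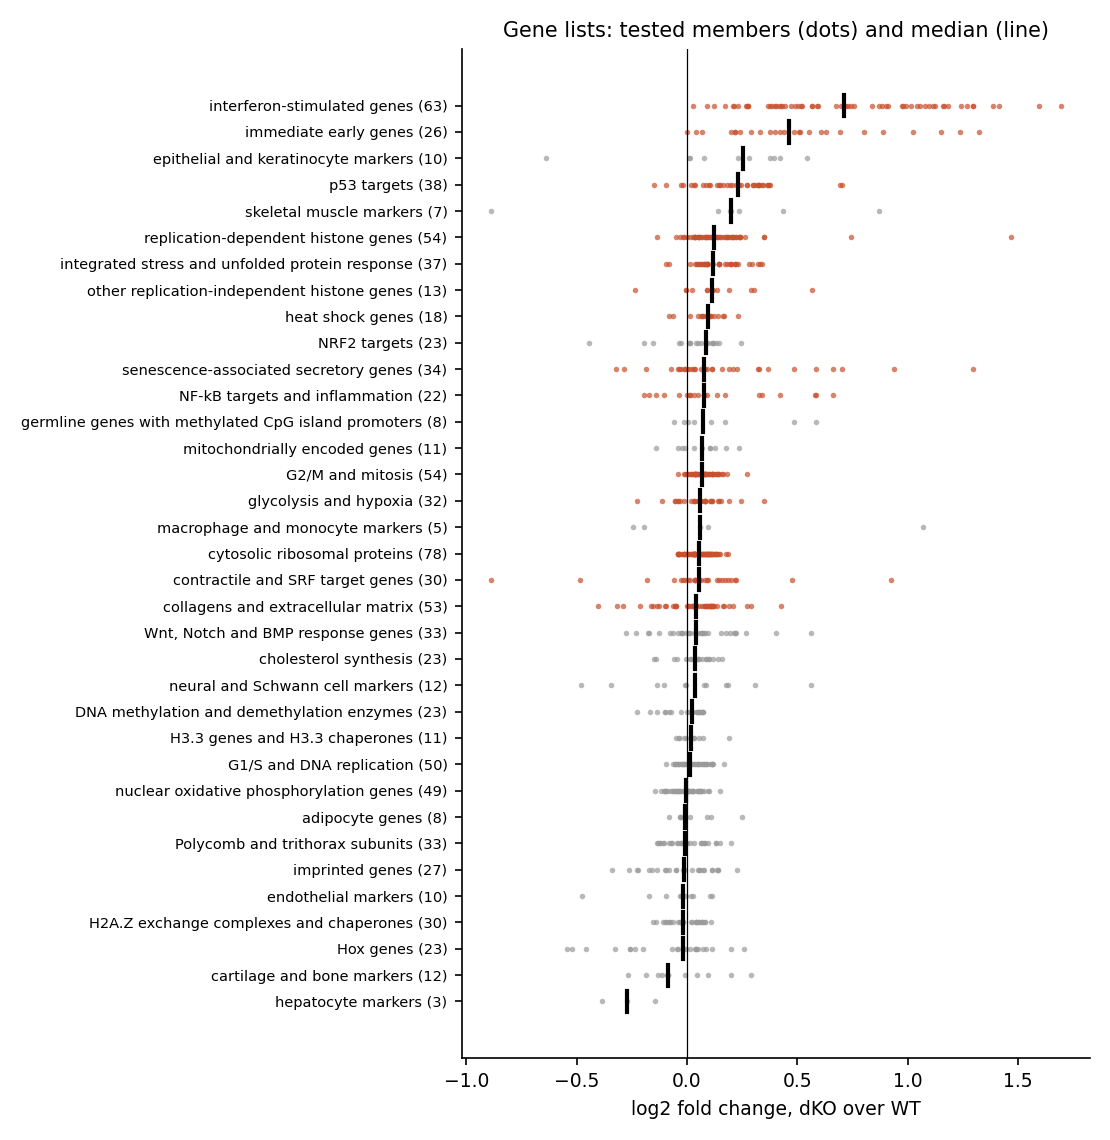
Log2 fold change (dKO over WT) of each tested member of 35 gene lists, with a line at the list's median and the number of members in brackets; lists in colour are the 14 past the camera test with the preset correlation. Of these, the interferon, immediate early, p53 and senescence lists also passed with an estimated correlation.

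Outside these lists, the genes with the smallest p-values among those lower in dKO were, after the targeted pair, Dpysl3, Zbtb26 and Sema3b. Dpysl3, which acts on the cytoskeleton, fell from 114.8 ± 2.98 to 96.0 ± 2.53 CPM (log2 change −0.26, SE 0.031; edgeR adjusted p = 5.81e-06). Zbtb26, a zinc finger protein, fell from 38.0 ± 0.222 to 29.4 ± 0.873 CPM (log2 change −0.37), and the semaphorin Sema3b fell from 45.5 ± 0.968 to 36.1 ± 1.12 CPM (log2 change −0.34).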

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

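The removal of trends with abundance and gene length, and the look at Gm12913, were chosen after the results were seen. No gene called here was called in the opposite direction under any of the alternatives. H2afz and H2afv passed under each, with log2 changes of −2.99 to −2.75 and −2.66 to −2.42 when single libraries were left out. With library totals alone, 559 genes were higher and 1339 lower, because the median of all genes moves by −0.033 (log2); with upper quartile factors the counts were 706 and 856. DESeq2 gave 375 lower genes and 29 changed at least 2-fold, and the cause was not tested. The threshold of 0.01 gave 468 higher, 217 lower and 32 at least 2-fold, by its construction. With single libraries left out, and so fewer samples, 573 to 907 genes were higher, 319 to 619 lower and 37 to 57 at least 2-fold. With the replicate number as a block, which the pairing check does not call for, 852 were higher, 581 lower and 55 at least 2-fold. An estimated correlation left 4 of 14 lists. The estimates for the lists lost lay between 0.051 and 0.594, above the preset 0.01. The interferon list kept its call at an estimate of 0.468, and the cause of the losses was not tested further. The interferon, immediate early and p53 lists passed under these alternatives, with the interferon median between 0.65 and 0.73. The senescence list did too, but lost its call with an estimated correlation once members shared with the interferon and p53 lists were left out (adjusted p = 0.0716), a test added after the data were seen. With the abundance trend removed, the matrix (adjusted p = 0.730) and ribosomal protein (adjusted p = 0.0591) lists no longer passed and 803 genes were higher and 655 lower; with the length trend removed, 1021 and 686. Targets of NRF2 passed camera under 8 alternatives with the preset correlation, but not with an estimated one (adjusted p = 0.498). Of the list tests under alternatives, 673 kept their side of the threshold, 16 lost a call and 11 gained one. Of the tests of named genes under alternatives, 2360 kept their side of the threshold, 204 lost a call, 31 gained one and 1 turned, Gm12913 at −0.44 without dKO replicate 3 and up to 5.35 without another library. Alternatives for promoter CpG content and for normalized values were not run. The self-test recovered 80% of 1.25-fold changes, which limits what can be said of smaller ones. It changed no gene with a log2 mean CPM under 1, so its rates do not cover such genes.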

Other observations

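The tests on macrophages, on the Cre virus and on both explanations of the H2A.Z reads left in dKO were chosen after the results were seen, as were the lists of zinc finger and ciliary genes. Lower genes included many that encode zinc finger proteins, which bind DNA, and proteins of cilia, motile or sensory. Of 350 tested zinc finger genes, 53 were lower and 2 higher in dKO over all genes (73 lower and 5 higher adjusted over the list alone), with a median log2 change of −0.09. Zfp157 fell from 43.5 ± 0.575 to 35.4 ± 0.759 CPM (SD, n = 3), and Zkscan3 (−0.20) and Zfp54 (−0.50) fell too. Of 101 ciliary genes, 24 were lower and 0 higher (29 lower and 1 higher adjusted over the list alone), with a median of −0.08. Ccdc39, which is needed to assemble motile cilia, fell by 0.60 on the log2 scale, Rsph9 by 0.50, and Wdr19, Lztfl1 and Cc2d2a, which act in transport along the cilium or at its base, by 0.21, 0.20 and 0.19. Both lists passed camera with the preset correlation and neither did with an estimated one (adjusted p = 0.130 and adjusted p = 0.140 with an estimated correlation).

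The nuclear RNA Malat1 made up 1.27 to 1.37% of the reads of the WT libraries and 1.09 to 1.18% of those of the dKO libraries. Gm12913, with 4392 reads in dKO replicate 3 and 40 to 79 elsewhere, is the gene with the largest fitted rise and was not tested further.

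The rise of interferon-stimulated genes in dKO is the first pattern weighed. Macrophages brought in with the dKO cells are argued against as the cells that carry the added reads. The highest summed level of their markers in a dKO library is 0.554% of the rise of 1691 CPM in the list. This covers only the 14 markers of 22 named that were measured, and does not say whether a few such cells acted on the fibroblasts. Scaling is excluded, with a lowest median of 0.677 (log2) over 4 other scalings against 0.71. A response to the Cre virus or to Cre itself could give the same rise and cannot be told apart from H2A.Z loss, because 0 dKO libraries had Cre and kept both genes. The same limit holds for the immediate early, p53 and stress lists and for each other difference between dKO and WT. Loss of H2A.Z is the biological explanation that the design names, and it stays open and untested.

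The second pattern is the H2afz and H2afv reads left in dKO. Cells in which both genes stayed intact are argued against as the only source, provided that such cells keep the WT ratio of both genes. They would then leave equal shares, and the share left was 1.25 times as high for H2afv (SD 0.046, n = 3). That SD leaves out the spread of WT, because each share was divided by the same WT mean. Expression of both genes in such cells was not measured. Reads from exons outside the deleted part, stable transcripts and cells with a single gene lost may each contribute. The 14.1% of H2afz left cannot be told apart by exon, because the table counts whole genes.

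The third pattern is the lower median of zinc finger and ciliary genes, of which 295 of 350 and 77 of 101 did not pass. A trend with abundance or with gene length is argued against as its whole cause, since at least 80.0% and 95.7% of each list's median was kept with the trend removed. These shares do not show that the pattern itself holds, because the lists were drawn up after lower genes had been seen and neither passed with an estimated correlation (adjusted p = 0.175 for each with the abundance trend removed). Variation between libraries that these genes share therefore stays open. A response to loss of H2A.Z may be a further explanation, as a hypothesis, and was not tested apart from the Cre virus.

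Regrouping the 6 libraries into 3 and 3 gives 10 splits, too few for a share under 0.05. The real split gave 957 genes higher, 668 lower and 53 changed at least 2-fold. The highest of the other splits gave 0 for each, so that 1 split reached each count. Each other split puts WT and dKO libraries on both sides, so a group difference widens the spread within each side. The 0 calls there are therefore no measure of what chance would give. For the gene lists, 2 of the 10 splits gave as many calls by camera with the preset correlation, the real one with 14 and the highest other with 18. The other 9 splits gave between 7 and 18 list calls with the preset correlation and 0 with an estimated one, where the real split gave 4. The median of the interferon list was 0.71 in the real split and at most 0.30 in size in the others. That of the immediate early list was 0.46 and at most 0.25, and that of the p53 list 0.23 and at most 0.11. Because the other splits mix the groups, they keep only part of any group difference, so their smaller medians are no support for these lists. With the preset correlation, camera called the interferon, immediate early and p53 lists in 9, 8 and 9 of the 9 other splits. The medians of the replication-dependent histone (0.12), ribosomal protein (0.06) and matrix (0.04) lists were exceeded in size by another split, with 0.16, 0.07 and 0.06.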
